A study of Mus musculus with 6 samples.

How the data were processed

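RNA was measured by sequencing in C17.2 cells, an established mouse neural stem and progenitor cell line. The labels describe 3 groups with 2 biological replicates each: control cells in serum-containing growth medium, cells treated with heme, and cells after culture in a neural induction medium containing BDNF, a neurotrophin, at 10 ng/ml. Per the labels' protocols, libraries were made from total RNA with the TruSeq RNA kit. The dose and duration of heme, the duration of induction and the medium of the heme-treated cells are not given in the sources used here.

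Per the submitters' processing notes, HISAT2, StringTie and edgeR were used on the GRCm38 (mm10) build, with no versions given. The authors deposited FPKM (fragments scaled by transcript length and by the mapped fragments of the library) and mean coverage per base for each assembled transcript of each library, in 1 table of 15113 transcripts at 7171 StringTie loci. Of these, 10948 transcripts have an Ensembl identifier and 4165 have only a StringTie identifier and no gene name. Transcript numbers in the table reach 125144, so the table holds part of a larger set, and the rule that chose it is not given. In 10895 cases the Ensembl identifier was found in GENCODE M21, a GRCm38 annotation, and 9534 of those had the same chromosome, start and end. Through the identifier, 30 gene names that had been turned into dates were restored. The authors also deposited, for heme and for neural induction, a table with a log2 fold change, a log2 mean abundance, a likelihood ratio score and a p-value per transcript.

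Read counts per gene are not used here, so no count model was run. Depth was read from the ratio of coverage to FPKM, which is 1 constant per library and gives the mapped bases behind the FPKM: 4.44 gigabases in control replicate 1, 4.35 in control replicate 2, 4.30 in heme replicate 1, 4.56 in neural induction replicate 1 and 4.14 in neural induction replicate 2. The heme replicate 2 column has no such constant (3.35 to 5.16), so no depth is given for it. No counting interval can be given from FPKM.

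The 2 heme columns were compared before averaging. The heme replicate 2 value of every transcript equals the replicate 1 value times a factor between 1.25 and 1.50, and the columns share all 1150 transcripts listed at 0. The pair was therefore counted as 1 sample, and the replicate 1 column was used, because the replicate 2 column has neither the total nor the coverage relation of the other libraries. This departs from the planned fit, which had 6 libraries and applied its filter over them. The change was made after the data were examined and after the calls of the 6-column fit had been seen. The number of those calls is given beside the heme result and, for all comparisons, in the part on processing at the end. The planned fit on all 6 columns and the mean of both heme columns were run as alternatives.

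Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend) on log2(FPKM + 1), over transcripts with at least 1 FPKM in at least 2 libraries. The fit held 5 libraries in 3 groups and left 2 residual degrees of freedom. The lone heme library is assumed to vary like the libraries of the other groups. Tests were two-sided, with Benjamini-Hochberg adjustment over all transcripts tested and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low transcripts. Sums of FPKM over the listed transcripts of a locus were tested in the same way, as an alternative added after seeing the data. Unlisted transcripts are not in these sums. The genes fixed in advance are given as such sums because the table splits some of them over several transcripts.

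The genes named are those with an adjusted p below 0.05, a mean of at least 5 FPKM, a gene symbol and no overlap between the groups (up to 10 per direction against control and 5 between heme and neural induction), plus 22 genes fixed in advance whatever their test, plus up to 4 members with the smallest p from each list described. The tests, the alternatives not marked as added, this rule and 32 gene lists were fixed before the data were examined. Names chosen after their values were seen are marked as such. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry beside it. With an estimated correlation, camera draws its p-value on the residual degrees of freedom of the fit, 2 here. Almost no list can pass on so few, so failing this form does not argue against a list. Fry was read both for a common direction and for change in either direction, and neither compares a list with other genes. Each library was also compared with the median of the other libraries, and the median of each list was ranked among 10000 random lists of the same size matched on mean expression.

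The fit was tested on simulated data made from the real means and spread. For the heme comparison, over 13737 transcripts, 1.2% of 2-fold, 18.7% of 4-fold and 40.7% of 16-fold changes were recovered, with 1.55 false calls among 41.1 calls on average. For neural induction, over 13737 transcripts, the shares were 10.3%, 33.3% and 53.1%, with 1.95 false calls among 65.9. Changes were placed only in transcripts with a mean above about 5 FPKM. The simulated noise was normal, with the spread of each transcript taken from the control and induction replicates. A transcript alike in those libraries could not jump in the simulated heme library by noise alone. The false calls given therefore do not cover all-or-none jumps in 1 library. Alternatives covered the replicate number as a block, the pseudocount (0.1 and 5), the filter, the scaling, the groups in the fit, the trend, a fold threshold, each library left out and the authors' deposited tables. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for the checks of the columns.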

Results

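Transcript levels were measured in C17.2 mouse neural progenitor cells under 3 conditions: growth medium (control), heme treatment and neural induction medium. The title of the study concerns erythroblasts, neurogenesis and mitochondrial dynamics, and the comparisons ask how heme and neural induction each change the transcriptome of these cells. The 5 distinct libraries rest on 4.14 to 4.56 gigabases of mapped sequence each, and the listed transcripts take 71.5% to 72.0% of it. Total FPKM over the listed transcripts lay between 398224 and 411657 in these libraries.

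The labels give 2 heme replicates, but the columns hold 1 set of measurements. Across 13963 transcripts, FPKM in heme replicate 2 divided by FPKM in heme replicate 1 lay between 1.25 and 1.5, with a mean of 1.37 and an SD of 0.0722. The same 1150 transcripts were listed at 0 in both columns, whereas 1212 transcripts were at 0 in only 1 of control replicate 1 and heme replicate 1, and 1228 in only 1 of the neural induction replicates. The columns were therefore counted as 1 sample. All heme results below rest on n = 1 library, without a replicate check of their own.

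**Figure D1:**
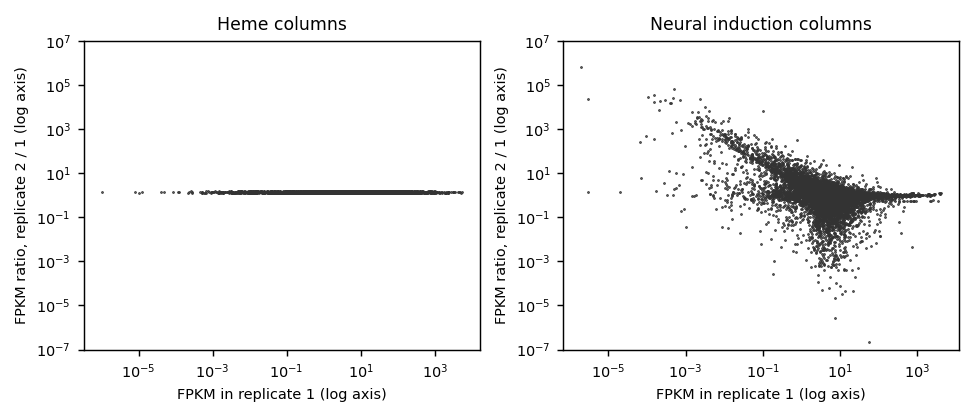
FPKM of replicate 2 divided by FPKM of replicate 1 against FPKM of replicate 1, with 1 point per transcript above 0 in both columns and log axes, for the heme columns (left) and the neural induction columns (right). The heme ratios stay between 1.25 and 1.5 at every abundance, while the neural induction ratios widen toward low FPKM.

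Control replicate 2 stood apart from the other libraries in genes of several fixed lists. Hmox1, the heme-degrading heme oxygenase 1, was at 222 FPKM there, against 43.7 in control replicate 1, 61.9 in heme replicate 1, and 79.4 and 46.2 in the neural induction replicates. Nqo1, an NRF2 target, was at 19.6 FPKM against 8.02 to 10.9 in the others, and Mki67, a proliferation marker, at 15.7 against 28.2 to 33.8. Mt1, a metallothionein chosen after its values were seen, was at 186 FPKM against 43.9 to 54.5. The heme and NRF2 response list had a median 1.54-fold above the median of the other libraries, with all 21 measured loci higher, above all 10000 random lists. Glycolysis and hypoxia genes (1.33-fold), heat shock genes (1.27-fold), p53 targets (1.21-fold) and G1/S genes (1.2-fold) were also higher there. G2/M genes (0.688-fold), cholesterol synthesis genes (0.776-fold) and mesenchymal genes (0.775-fold) were lower. The median absolute log2 difference between the control replicates was 0.19 over 5985 loci, against 0.075 between control replicate 1 and heme replicate 1. These are descriptions of single libraries, not tests of a condition.

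**Figure D2:**
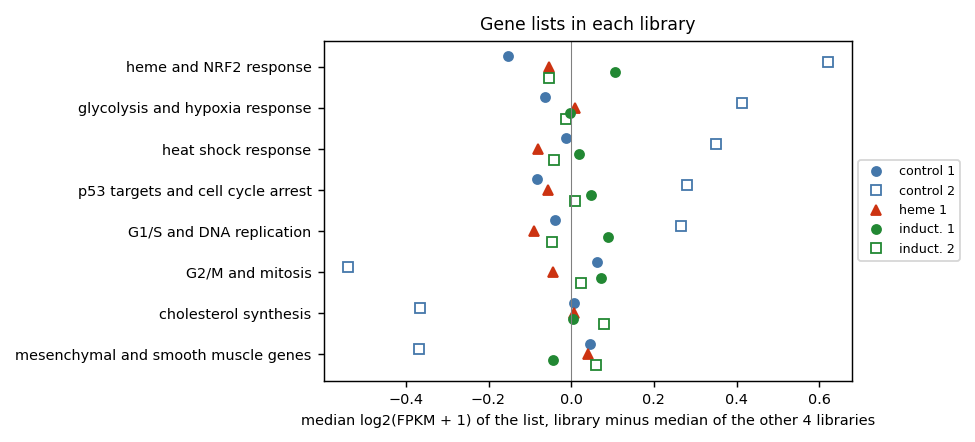
Median over the loci of 8 gene lists of log2(FPKM + 1) in each library minus the median of the other libraries, with 1 point per list and library. Control replicate 2 (open blue squares) lies at 0.62 for the heme and NRF2 response and at -0.54 for G2/M and mitosis.

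Heme treatment was compared with control to ask which transcripts it changes. In the heme library, single transcripts of Rpl3 and Rpl7a, which encode proteins of the large ribosomal subunit, of Tuba1b, an alpha-tubulin, and of Rhog, a small GTPase, fell. Rpl3 transcript ENSMUST00000081650 (chromosome 15, 80077796 to 80083353, GRCm38) was at 57.1 FPKM against 267 and 285 in the controls, a log2 fold change of -2.25 ± 0.088 (SE). Tuba1b ENSMUST00000077577 (chromosome 15, 98931425 to 98934565) was at 30.4 FPKM against 579 and 614 (-4.25 ± 0.11). Rpl7a ENSMUST00000143678 (chromosome 2, 26911006 to 26913318) was at 1.16 FPKM against 84.8 and 77.3 (-5.25 ± 0.13), and Rhog ENSMUST00000098230 (chromosome 7, 102239123 to 102250123) at 0.402 against 26.2 and 25.8 (-4.27 ± 0.21). Adjusted p in limma was 0.0245 for Rpl3, 0.0121 for Tuba1b and Rpl7a, and 0.0445 for Rhog.

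Summed over the listed transcripts of a locus, these genes differed little from control. The Rhog locus was at 26.3 FPKM in the heme library against 27.6 and 26.4, because transcript ENSMUST00000106923 stood at 25.9 FPKM there against 1.42 and 0.605. The locus shared by Tuba1b and Tuba1a was at 991 FPKM against 950 and 931, and the Rpl7a locus at 885 against 899.5 and 869. The Rpl3 locus was at 340 FPKM against 418 and 388 (-0.24 ± 0.087, adjusted p = 0.998 in limma). Unnamed transcripts at the loci of Larp1, Arhgdia, Ecm1, Wsb2 and Fgfr1 also fell. So did MSTRG.4861.1, unnamed and the only listed transcript at its locus (chromosome 12, 109894378 to 109895125). It was listed at 0 in the heme library against 44.9 and 44.0 FPKM. At loci listed at 0, lost output and reads moved to an unlisted transcript cannot be told apart, here and for the locus sums below. At the Wsb2 locus the called transcript was listed at 0 in the heme library, while ENSMUST00000031309 was at 54.6 FPKM there against 4.80 and 4.63. On locus sums, chosen after seeing the data, limma called 3 unnamed loci lower, MSTRG.4861, MSTRG.4724 and MSTRG.7695, each listed at 0 in the heme library and named after their values were seen.

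**Figure D3:**
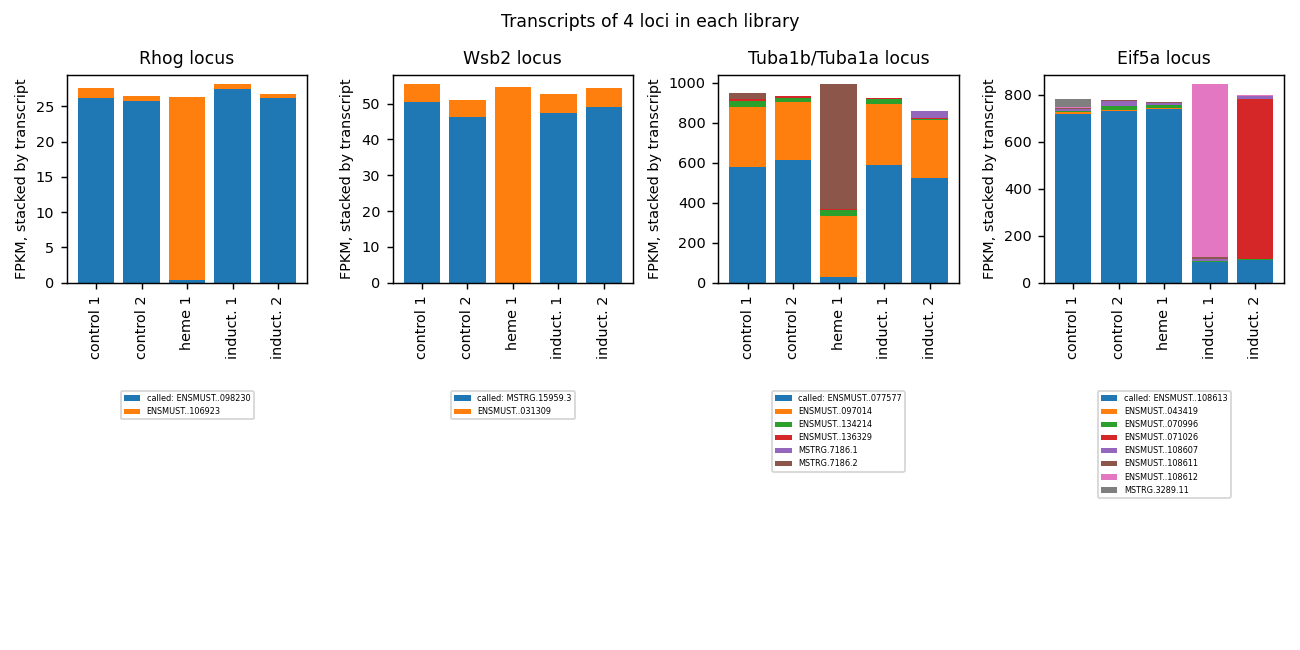
FPKM of each listed transcript at 4 loci, stacked, in the 5 distinct libraries, with the called transcript at the base of each bar. At the Rhog, Wsb2 and Tuba1b/Tuba1a loci the heme library, and at the Eif5a locus both neural induction libraries, carry most FPKM on another transcript, while the height of the bars changes little.

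In all, limma called 10 of 13737 transcripts lower and 0 higher in the heme comparison, with 680 at an unadjusted p below 0.05, where 687 would be expected by chance. All of these calls were lost when any 1 control or induction library was left out. Each such fit has 1 residual degree of freedom fewer, so the loss does not show dependence on that library. With the replicate block, also with 1 fewer, limma called 0, with 593 at an unadjusted p below 0.05. The filter over the 5 libraries asked for 1 FPKM in at least 2 of them. A transcript found only in the heme library was therefore dropped and could not be called higher. Arhgdia ENSMUST00000106197, at 29.4 FPKM there against 0.0253 and 0.0272 in control, was such a case. A fit without the filter also called none higher. Fitted on all 6 columns, as the design was written, such transcripts are kept. That comparison gave 417 calls (251 higher, 166 lower) and a median log2 fold change of 0.22 over all transcripts. The authors' deposited table for heme holds 1094 transcripts with a Benjamini-Hochberg adjusted p below 0.05 (527 higher, 567 lower), and its log2 fold changes match the ratio of heme replicate 1 to control replicate 1 within 0.1 for 100% of transcripts. That deposited table therefore compares 2 libraries, not the conditions.

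Of the 22 genes fixed in advance, 15 are listed, and none passed in the heme comparison, summed over its locus or by transcript. Map2, a neuronal microtubule protein, was at 18.6 FPKM in the heme library against 10.4 ± 0.031 (SD, n = 2) in control (log2 fold change 0.78 ± 0.21, adjusted p = 0.989 in limma). Alas1, the rate-limiting enzyme of heme synthesis, was at 6.27 FPKM against 10.4 ± 1.29 (-0.65 ± 0.20), and Tfrc, the transferrin receptor, at 61.9 against 110 ± 40.1 (-0.76 ± 0.32). The Tfrc value depends on control replicate 2 (138 FPKM, against 81.2 in control replicate 1) and was -0.39 without it. Hmox1 had a log2 fold change of -0.67 ± 1.00, set by the 222 FPKM in control replicate 2, and of 0.49 without that library, the opposite direction. The ferritin genes Fth1 (-0.020 ± 0.18) and Ftl1 (-0.13 ± 0.21), Slc7a11 (-0.18 ± 0.57) and Nqo1 (-0.53 ± 0.53) differed by at most about their error. Control replicate 2 was the highest library for these 4 genes, and without it each turned, to 0.14 for Fth1, 0.093 for Ftl1, 0.049 for Slc7a11 and 0.060 for Nqo1. Control replicate 1, then the only control, was the lowest library for Hmox1, Fth1, Ftl1 and Nqo1. A positive value against it was therefore fixed in advance for those genes. Nes had a log2 fold change of -0.035 ± 0.11, Sox2 of 0.21 ± 0.22, Tubb3 of 0.19 ± 0.19 and Mki67 of 0.54 ± 0.45. Control replicate 2 was the lowest library for Sox2, Tubb3 and Mki67. Adjusted over the list alone, the lowest p among these genes was 0.203, for Alas1 and Map2.

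In the heme library Dnm1l, the fission GTPase, was at 49.2 FPKM against 48.3 ± 0.350 (SD, n = 2), Mfn1, a fusion GTPase, at 16.0 against 15.4 ± 0.692, and Fis1 at 28.0 against 28.4 ± 7.11. The Fis1 mean joins unlike controls (33.4 and 23.4 FPKM), and without control replicate 2 its log2 fold change was -0.25. Other loci of the fusion and fission list, chosen after their values were seen, lay further from control: Mff at 15.4 FPKM against 26.3 and 20.4, Mief1 at 3.12 against 4.54 and 8.13, Mtfr1 at 41.8 against 33.6 and 18.8, and Chchd3 at 61.9 against 46.5 and 37.7 (adjusted p = 0.998 for each in limma). The induction replicates differed from each other as well, with Mtfr1 at 35.7 and 17.5 FPKM and Chchd3 at 44.5 and 61.3. Mief1 was at 5.38 and 7.92 there, and Mff at 20.4 and 23.8. At the level of transcripts, 0 of 25 tested members of the fusion and fission list passed over all transcripts, and 1 adjusted over the list alone: Mff ENSMUST00000162794 (0.564 FPKM against 13.2 and 11.2, -3.07 ± 0.37, adjusted p over all transcripts = 0.206 in limma). In the biogenesis and mitophagy list 0 of 17 passed and 1 adjusted over the list alone, Ssbp1 ENSMUST00000117411 (-3.13 ± 0.26, adjusted p = 0.106 in limma). All 13 transcripts of mitochondrial DNA had a positive log2 fold change with a median of 0.15, and 0 passed. That list was at 0.753-fold of the other libraries in control replicate 1 and 0.856-fold in induction replicate 1, with 0 of 10 loci higher in each. It was at 1.15-fold in control replicate 2, 1.09-fold in the heme library and 1.06-fold in induction replicate 2, with 10 of 10 higher in each. Its median over locus sums was 0.15 with both controls and 0.40 without control replicate 2.

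Among the other lists, 0 of 33 transcripts of the heme and NRF2 response, 0 of 24 of iron handling and 0 of 21 of heme synthesis and transport passed, with medians of -0.24, 0.091 and -0.067 on the log2 scale. The heme and NRF2 response is also the list in which control replicate 2 was 1.54-fold above the other libraries. Over locus sums its median was -0.22 with that library and 0.055 without it. Control replicate 1, the control left, was low for this list, at 0.900-fold of the other libraries with 2 of 21 loci higher. In the neuronal list 10 of 11 transcripts were above control with a median of 0.40, and 0 passed. This list was at 0.828-fold of the other libraries in control replicate 2, with 0 of 6 loci higher, and at 1.09-fold in the heme library, with 6 of 6 higher (0.13 on the log2 scale, upper limit of random lists 0.11). Its median over locus sums was 0.22 with control replicate 2 and 0.039 without it. None of the 27 lists with enough members passed camera in limma, with adjusted p from 0.220 (glycolysis and hypoxia, median -0.25) to 0.925 at the preset correlation and 0.952 with an estimated correlation. Of the ribosomal protein list, 1 of 80 transcripts passed, the Rpl3 transcript above. Adjusted over the list alone, 2 of 48 transcripts of YAP and SRF targets passed, with opposite signs and both of Amotl2, and 1 of 34 of the G1/S list. By fry, 0 of the 27 lists moved in a common direction, and 7 held change in either direction, led by mitochondrial fusion and fission and by YAP and SRF targets (adjusted p = 0.00213 each). On locus sums, chosen after seeing the data, 0 of 26 lists held change in either direction (0.851 for both of these lists). The synaptic, oligodendrocyte and endothelial lists had 2, 4 and 3 tested transcripts, of which 0 passed over all transcripts and 0, 0 and 2 adjusted over the list alone, and no gene of the erythroid or microglial lists is listed.

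Neural induction was compared with control to ask what the induction medium changes in these progenitors. Limma called a single transcript lower, of Eif5a, a translation factor: ENSMUST00000108613 (chromosome 11, 69916720 to 69921386) was at 86.8 and 94.8 FPKM against 719 and 732 in control, a log2 fold change of -2.99 ± 0.075 (adjusted p = 0.0296 in limma). The remaining Eif5a signal lay on ENSMUST00000108612 in induction replicate 1 (733 FPKM, against 4.89 and 2.19 in control) and on ENSMUST00000071026 in induction replicate 2 (679 FPKM, against 0.0672 and 0.456). The sum over the Eif5a locus was 844 and 799.8 FPKM after induction against 781 and 778 in control (0.076 ± 0.069). On locus sums, chosen after seeing the data, the Gm26712 locus (chromosome 6, 57689433 to 57689649), named after its values were seen, was called lower, at 0.179 and 0.216 FPKM after induction against 25.3 and 22.2 in control (-4.36 ± 0.18, adjusted p = 0.046 in limma). Its only listed transcript was not called in the limma fit of all transcripts (adjusted p = 0.176).

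Genes of progenitor and neuronal identity did not pass. Nes, an intermediate filament of neural progenitors, was at 115 ± 11.2 FPKM after induction against 132 ± 0.011 in control (SD, n = 2 each, log2 fold change -0.19 ± 0.091), and Sox2, a progenitor transcription factor, at 19.3 ± 0.615 against 16.1 ± 3.63 (0.26 ± 0.18). Control replicate 2 was the lowest library for Sox2 (13.6 FPKM, against 18.7 in control replicate 1), and without it the log2 fold change was 0.045. Tubb3, a neuronal tubulin, was at 12.5 ± 1.49 FPKM against 12.1 ± 1.12 (0.042 ± 0.15), and Map2 at 13.6 ± 2.63 against 10.4 ± 0.031 (0.34 ± 0.17, adjusted p = 0.935 in limma). Mki67 had a log2 fold change of 0.37 ± 0.37 and Hmox1 of -0.70 ± 0.82, both with control replicate 2 as the extreme library. Without it both turned, to -0.15 for Mki67 and 0.46 for Hmox1. For Hmox1 control replicate 1, the control left, was the lowest library, so a positive value was fixed in advance. Slc7a11 had a log2 fold change of -0.57 ± 0.46, Tfrc of -0.35 ± 0.26 and Nqo1 of -0.34 ± 0.43. Those of Alas1 (-0.035 ± 0.16), Fth1 (-0.032 ± 0.15) and Ftl1 (-0.070 ± 0.17) were smaller. Control replicate 2 was the highest library for each of these genes from Slc7a11 to Ftl1. Dnm1l was at 47.6 ± 1.66 FPKM against 48.3 ± 0.350, Mfn1 at 15.3 ± 0.174 against 15.4 ± 0.692 and Fis1 at 28.8 ± 2.59 against 28.4 ± 7.11, with a log2 fold change for Fis1 of 0.035 with control replicate 2 and -0.21 without it. Adjusted over the list alone, the lowest p among the 15 listed genes was 0.844. Dcx, Gfap, Ntrk2, Mfn2, Opa1, Ppargc1a and Tfam were not analysed here.

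Limma called 1 of 13737 transcripts lower and 0 higher after neural induction, with 684 at an unadjusted p below 0.05. This call was lost when any 1 control or induction library was left out. Each such fit has 1 residual degree of freedom fewer, so the loss does not show dependence on that library. The Eif5a transcript was at 86.8 and 94.8 FPKM after induction against 719 and 732 in control. With the replicate block, also with 1 fewer, limma called 0, with 503 at an unadjusted p below 0.05. Fitted on all 6 columns, as the design was written, more transcripts were called, 43.0% of them higher. The authors' deposited table for neural induction holds 1088 transcripts below 0.05 after Benjamini-Hochberg adjustment (537 higher, 551 lower), and its log2 fold changes match the ratio of neural induction replicate 1 to control replicate 1 within 0.1 for 100% of transcripts.

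None of the 27 lists passed camera after neural induction, with adjusted p from 0.177 to 0.972 at the preset correlation and at least 0.971 with an estimated correlation. Of the G2/M list 34 of 45 transcripts were above control (median 0.27) and 0 passed, and of the cholesterol synthesis list 22 of 30 were above control (median 0.16) and 0 passed. Both lists were low in control replicate 2 (0.688-fold and 0.776-fold of the other libraries). In the mitochondrial fusion and fission list 0 of 25 passed over all transcripts and 1 adjusted over the list alone, Dnm1l ENSMUST00000023477, at 41.6 and 40.8 FPKM against 1.73 and 1.68 (3.96 ± 0.29, adjusted p over all transcripts = 0.179 in limma), while the sum over the Dnm1l locus stayed at the values above. In the nuclear respiratory chain list 58 of 91 transcripts were above control (median 0.036), with 0 calls over all transcripts and 4 adjusted over the list alone. Adjusted over the list alone, 2 transcripts also passed among YAP and SRF targets, 2 among ribosomal proteins, and 1 each among mesenchymal genes, cholesterol synthesis genes and interferon response genes. By fry, 0 of the 27 lists moved in a common direction, and 4 held change in either direction, with the lowest adjusted p for YAP and SRF targets (0.000565). On locus sums 0 of 26 did (0.886 for YAP and SRF targets).

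When lists were tested on sums over loci, a choice made after seeing the data, 7 lists passed camera in the heme comparison and 9 after neural induction at the preset correlation. For heme these were glycolysis and hypoxia (median -0.20, adjusted p = 0.0375 in limma's camera), heat shock (-0.22) and G1/S (-0.15), lower, and G2/M (0.21), cholesterol synthesis (0.14), mesenchymal (0.18, adjusted p = 0.0328) and neuronal genes (0.22, adjusted p = 0.0447), higher, with 0.0179 for the 4 others. Lower after neural induction were the glycolysis and hypoxia list (median -0.21, 2 of 22 loci above control, adjusted p = 0.00372 in limma's camera), YAP and SRF targets (median -0.16, 4 of 21, 0.00914), mitochondrial biogenesis and mitophagy (median -0.21, 1 of 11, 0.0135), heat shock genes (median -0.19, 0 of 13, 0.0135), the heme and NRF2 response (median -0.22, 3 of 22, 0.0159) and G1/S genes (median -0.12, 4 of 25, 0.0159). Higher were cholesterol synthesis (median 0.21, 19 of 19 above control, adjusted p = 0.000403), G2/M (median 0.26, 26 of 28 above control, adjusted p = 0.000497) and mesenchymal genes (median 0.18, 16 of 18 above control, adjusted p = 0.0307). With an estimated correlation none passed for heme or, with adjusted p of at least 0.960, for neural induction. On 2 residual degrees of freedom that form could hardly pass any list. For YAP and SRF targets after neural induction the estimated correlation was -0.028, below the preset 0.01. The adjusted p of that list in camera still went from 0.00914 to 0.960. Except for mitochondrial biogenesis and mitophagy, which lay within the limits of its random lists there (0.16, upper limit 0.18), each of these lists was displaced the opposite way in control replicate 2. Without that library the only list to pass for heme at the preset correlation was that of mitochondrial DNA (median 0.40). It did not pass with an estimated correlation, but that form then had 1 residual degree of freedom fewer still. The 7 lists above had medians of -0.054 to 0.039. For neural induction 0 passed, and the medians were 0.024 for glycolysis and hypoxia, 0.14 for the heme and NRF2 response, 0.015 for heat shock, 0.014 for G1/S, -0.0059 for G2/M and -0.0035 for mesenchymal genes, each on the other side of 0. Those of cholesterol synthesis (0.044), YAP and SRF targets (-0.080) and mitochondrial biogenesis and mitophagy (-0.057) kept their sign. Control replicate 1, then the only control, was low for the heme and NRF2 response (0.900-fold of the others) and glycolysis and hypoxia (0.957-fold). It was high for G2/M (1.04-fold) and mesenchymal genes (1.03-fold). In both induction libraries YAP and SRF targets (0.962-fold and 0.972-fold of the other libraries) and mitochondrial biogenesis and mitophagy (0.915-fold and 0.934-fold) lay below the lower limit of their random lists.

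Heme and neural induction were also compared directly. Eif5a ENSMUST00000108613 was higher in the heme library, at 741 FPKM against 86.8 and 94.8 (3.02 ± 0.092, adjusted p = 0.0096 in limma). Rpl7a ENSMUST00000143678 (-5.22 ± 0.13), Rhog ENSMUST00000098230 (-4.31 ± 0.21), Tuba1b ENSMUST00000077577 (-4.14 ± 0.11) and Rpl3 ENSMUST00000081650 (-2.84 ± 0.088) were lower in the heme library than after induction. In total 1 transcript was higher and 10 were lower in the heme library out of 13737, with 682 at an unadjusted p below 0.05. No list passed camera (adjusted p from 0.624 to 0.983) or fry for a common direction, and 7 of 27 passed fry for change in either direction, with 0 of 26 on locus sums. The transcript calls were lost when any 1 control or induction library was left out. Each such fit has 1 residual degree of freedom fewer, so the loss does not show dependence on that library. Fitted on all 6 columns, as the design was written, more transcripts were called. Of those, 62.3% were higher in the heme library, the opposite balance, and 56.7% after median-of-ratios scaling. With both heme columns in the fit, a transcript found only under heme passes the filter, which it cannot with 1 heme library.

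No transcript was called in both comparisons against control, where independent lists would share 0.000728. With 10 and 1 calls an overlap could hardly occur, so its absence does not tell shared from separate effects. Across 13737 transcripts the log2 fold changes of heme and of neural induction had a Pearson r of 0.39, and simulated unchanged groups against the same controls gave a mean r of 0.41 (0.36 to 0.45 over 100 simulations). The covariance was 0.32 against a simulated 0.35, a difference of -0.035. Genes are not independent replicates, and a split of the controls, which would leave 1 library in each part, was not made.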

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

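All tests in this part were chosen after the result was seen, except the correction for GC content and length.

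The heme replicate 2 column, which enters no comparison, has a total of 554543 FPKM over the listed transcripts, above both control libraries. In 3 other pairs (the control replicates, control replicate 1 with heme replicate 1, and the induction replicates) the log2 ratio spread more among weak transcripts than among strong ones, by a factor of 8.43 to 9.69 between transcripts in the lowest and in the highest of 5 equal classes of abundance. In the heme pair that factor was 1.00, which argues against a separately sequenced library. The ratios follow a uniform distribution between 1.25 and 1.5 (Kolmogorov-Smirnov distance 0.00288, where 0.0115 is the 5% limit for a fixed distribution), and FPKM in this column carries up to 9 decimals against 6 elsewhere, consistent with values computed from the replicate 1 column with a factor drawn per transcript. How the column came about cannot be seen in these data, and no biological explanation was tested.

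Control replicate 2 differs from the other libraries in stress, glycolysis and cell cycle genes, and without it the lists passing camera on locus sums went from 7 to 1 for heme and from 9 to 0 for neural induction. None of these lists passed with an estimated correlation, with or without control replicate 2. That form could hardly pass any list on so few residual degrees of freedom. Over loci with 1 listed transcript the median deviation of control replicate 2 was 2.40 times that of the next library. This argues against the division of reads among listed transcripts. Reads lost to unlisted transcripts at these loci cannot be seen. After removal of the trend on GC content and length, the median of the heme and NRF2 response list there was 0.67, against 0.62 before and a random limit of 0.11, which argues against that bias as the whole cause. An exchange of labels with the heme library could place a heme response in this library (1.54-fold), but Tfrc (1.71-fold) and Alas1 (1.16-fold), genes that iron or heme lowers, were also higher there and lowest in the heme library (61.9 and 6.27 FPKM), which runs the way the labels say, so with 1 heme library this cannot be told apart from a different state of that culture. Neither a single wrong label from outside nor culture density or medium age was tested, and a biological difference of that culture stays open.

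Of the 10 transcripts lower in the heme library, 9 lie at loci with several listed transcripts. The median absolute log2 fold change of those locus sums was 0.075, consistent with reads assigned to other transcripts of the same locus. The lowest locus value was -0.24 (Rpl3), which argues against lower output of the whole locus as the cause. The highest was 0.57 (Arhgdia), and no locus passed its test (lowest adjusted p = 0.527 in limma). Large transcript differences were not particular to the heme library. Of 8247 transcripts with a mean of at least 5 FPKM, 16.3% differed over 2-fold between the control replicates. The shares were 16.1% between the induction replicates and 15.4% between control replicate 1 and heme replicate 1. Over loci they were 2.47%, 1.94% and 1.69%. Whether the switch lies in the cells or in the assembly of 1 library stays open, since there is no second heme library.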

How the results depend on the processing

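The fit on all 6 columns was the one planned, and it became an alternative only after seeing the data. Its rescaled form, the mean of the heme columns, locus sums and the crossed pairing were chosen after seeing the data, and the cause of each change was not tested unless given. Replicate differences of control and of neural induction were hardly correlated (-0.015 over transcripts, -0.11 over loci). This shows no pairing by replicate number but cannot exclude one, since control replicate 2 stood apart. With the replicate block, and with the crossed pairing, the calls were 0 for heme, 0 for neural induction and 0 between them, with 1 residual degree of freedom fewer (limma, 503 to 664 at an unadjusted p below 0.05).

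Calls for heme (10 in the fit reported) became 6 without a filter and 6 with quantile normalization, 0 with only the 2 groups in the fit, 0 without the intensity trend (959 at an unadjusted p below 0.05), 3 on locus sums and 0 on locus sums without control replicate 2. The single call for neural induction became 0 without a filter, 0 without the trend and 0 on locus sums without control replicate 2. Between heme and induction, 11 calls became 1 with only the 2 groups, 0 without the trend, 4 on locus sums and 0 on locus sums without control replicate 2. Leaving out any control or induction library kept none of the calls of the fit reported. Leaving out heme replicate 1 only puts the replicate 2 column in its place, and leaving out heme replicate 2 is the fit reported. These heme runs gave up to 10 calls for heme, 1 for neural induction and 12 between them. Leaving out a control or induction library also took 1 residual degree of freedom from the fit. The mean of the heme columns gave 11, 1 and 12. Using all 6 columns gave 417, 86 and 432 calls, with median-of-ratios scaling 741, 253 and 780, and on locus sums 207, 51 and 210, where the repeated heme values shrink the estimated spread by construction. The authors' deposited tables give 1094 and 1088. All other alternatives kept each count within 1.5 times. No transcript was called in both comparisons except with all 6 columns (39), with these rescaled (102), with their locus sums (19) and in the authors' deposited tables (487, an overlap counted after seeing the data), which share control replicate 1.

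Lists passing camera numbered 0 in both comparisons. Leaving out a library gave 0 to 7 for heme and 0 to 8 for neural induction, the highest when control replicate 2 was the only control. The stricter filter gave 2 for neural induction, locus sums gave 7 and 9, locus sums without control replicate 2 gave 1 for heme, and locus sums of all 6 columns 1 for neural induction. An estimated correlation, and fry for a common direction, gave 0 on transcripts and on locus sums. For the estimated correlation another count was hardly possible on 2 residual degrees of freedom.

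No named value changed sign where it was called. Of the values of the named transcripts under alternatives, 102 kept their side of the threshold and 88 no longer passed it. Of those of the genes fixed in advance, 527 moved by less than the spread of replicates and 41 by more. Leaving out a control or induction library moves a value by less than this spread by construction. The filter, the trend and the groups in the fit do not move it at all. The 527 therefore do not show stability, and include Hmox1 for heme, which turned without control replicate 2. DESeq2 was not run because the values are not counts. With 2 residual degrees of freedom, simulated 16-fold changes were recovered in 40.7% of cases for heme and 53.1% for neural induction. For 4-fold changes the shares were 18.7% and 33.3%. These changes were placed only in transcripts with a mean above about 5 FPKM.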

Other observations

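The tests here were chosen after the result was seen. mt-Co1, a subunit of cytochrome c oxidase, was at 3162 FPKM in control replicate 1 against 4594 in control replicate 2, 4283 in the heme library and 3840 and 4384 after induction, and mt-Cytb at 2480 against 3678, 3429, 2899 and 3302. The locus of mt-Atp8, mt-Atp6 and mt-Co3 was lowest in induction replicate 1 instead (9814 FPKM, against 10993 in control replicate 1), as was mt-Nd3 (865 against 866). Summed over loci and without control replicate 2, the mitochondrial DNA list passed camera for heme (median 0.40, 10 loci, adjusted p = 0.000542 in limma) and not for neural induction (median 0.28, adjusted p = 0.0728). With an estimated correlation the list did not pass for heme, which so few residual degrees of freedom would give for almost any list. With both controls the locus medians were 0.15 and 0.031, so the call rests on control replicate 1 alone.

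A pair of Amotl2 transcripts, from an angiomotin family gene, parted control from both other conditions. ENSMUST00000145913 was listed at 0 and at 0.0566 FPKM in control, 20.9 in the heme library and 22.8 and 22.5 after induction. ENSMUST00000153911 was at 22.1 and 22.2 FPKM in control, 0.270 in the heme library and 0.184 and 0.203 after induction. The sum over the Amotl2 locus was 55.6 and 53.2 FPKM in control, 54.2 in the heme library and 54.8 and 54.7 after induction. Neither transcript passed over all transcripts (lowest adjusted p = 0.124 for heme and 0.194 for neural induction in limma).

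Col1a1, a fibrillar collagen, and Postn, periostin, were chosen after their values were seen. Col1a1 was at 1053 and 807 FPKM in control, 1029 in the heme library and 1010 and 1075 after induction, and Postn at 309 and 239, 320, and 305 and 318.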
